A study of Homo sapiens with 6 samples.

How the data were processed

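DNA enriched with an antibody against 5hmC was sequenced from MDS-L cells with a MOCK vector or with SIRT1 overexpression, with 2 libraries per group. Per the labels' protocols, cells were grown with 10% FBS and 30 ng/mL IL-3 and their genomic DNA was sonicated before enrichment. Each library had its own peak list, so peaks were called per library and not on pooled samples. Per the submitters' processing notes, bcl2fastq 2.18, BWA 0.7.5a and MACS2 were used with the build hg19 (GRCh37). The MACS2 version and its control are not given in the sources used here. In the deposited lists the authors give each peak a fold enrichment, a −log10 p-value, a −log10 q-value and a score, all as the peak caller wrote them. From the values, the lists hold peaks with an unadjusted p of up to 0.001, and the deposited score is the whole part of 10 times the −log10 p. A fold or −log10 q belongs to the peak in its own list and was used to describe, rank or filter peaks. The same cuts were applied to every list, and the numbers of peaks and regions that passed were compared between libraries and groups. Background levels differed between the lists, so a cut does not ask for the same signal in each. Of the peaks, 93.5% in MOCK 1, 92.4% in MOCK 2, 92.1% in SIRT1OE 1 and 89.8% in SIRT1OE 2 had a q of up to 0.05.

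Chromosomes 1 to 22 and X were used, and chromosome Y was left out. The fold enrichment and −log10 p of a peak were solved together for a whole number of fragments at the summit and a local background, with a tolerance of 0.001 on −log10 p, which succeeded for 100.0% of peaks in every library. The most frequent background was taken as the genome background of the library, and the local background was divided by it. This ratio differs along the genome. At the second-ranked region of the MOCK pair it was 51.6 in both libraries, as a control shared by these libraries would give, and it is called the input background for that reason. The recovery was tested on 2000 simulated peaks and found 2000 of them. No read totals were used here, so the background level stands for depth. A lower depth or a higher background makes weak sites less likely to be called, and the recovery of peaks by the other library of a group was used as the measure of precision.

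Peaks were shared when they overlapped by at least 1 bp, and overlapping peaks of the 4 libraries were joined into regions. Random placements were drawn 100 times with a fixed seed, on the same chromosome or inside the same 5 Mb bin, leaving out stretches of 1 Mb or more without a peak. In a test on simulated data with 1000 planted regions, 1036 regions specific to the SIRT1OE pair and 19 specific to the MOCK pair were found. The planted regions had the same coordinates in both SIRT1OE lists. The test therefore checked the counting only and does not measure how often real regions are found. Single values were compared between groups by exact two-sided permutation tests. The regions named were fixed by a rule before the data were examined: 12 regions per class by the lower of the 2 within-library percentiles of −log10 q, and 6 called in all 4 libraries. The rule asked for regions in genes, and coordinates took their place because the annotation at hand was for another build. For the same reason the annotation of peaks, the gene lists, the sequence under peaks and the SIRT1 and TET2 genes were not analysed here.

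Peaks per 5 Mb bin were compared after the values had been seen. Bins with at least 40 peaks over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 (trended empirical Bayes, Benjamini-Hochberg adjustment at 0.05) on log2 of the peaks plus 0.5 per 10000 peaks of the library. On simulated data of 350 bins, 65% of bins changed 2-fold and 96% of bins changed 4-fold were called, with 2 false calls among 150 unchanged bins. The simulation changed 100 bins by each size and drew Poisson counts without further spread between libraries. These shares are therefore not the power or error rate of the real comparison. Alternatives were stricter thresholds on −log10 q and fold (5 each), equal numbers of peaks, an overlap of 50% of the shorter peak, summits within 500 bp, a replicate block and leaving out each library. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.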

Results

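Hydroxymethylated DNA immunoprecipitation sequencing (hMeDIP-seq) was used to map 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine that TET enzymes make, in MDS-L, an established human myelodysplastic syndrome cell line. Cells had been transduced with a lentivirus carrying SIRT1, a protein deacetylase, or with a MOCK vector, and the question was where 5hmC differs when SIRT1 is overexpressed, in a study of SIRT1 and the function of TET2. The libraries fell into 2 groups, 2 MOCK and 2 SIRT1OE (SIRT1-overexpressing). The 2 input samples were not analysed here. On chromosomes 1 to 22 and X the lists held 12091 peaks in MOCK 1, 8066 in MOCK 2, 10724 in SIRT1OE 1 and 9287 in SIRT1OE 2. Read totals were not used here. The background level recovered from the peak values, which rises with depth and fragment length, was 1.73 overlapping fragments in MOCK 1, 1.58 in MOCK 2, 2.56 in SIRT1OE 1 and 1.85 in SIRT1OE 2. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. With 2 libraries against 2, the smallest p that an exact permutation test allows is 0.33, so no comparison of single values by this test, the one chosen here, could pass 0.05.

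The first comparison asked whether SIRT1 overexpression went with more or fewer 5hmC peaks. The number of peaks did not separate the groups: MOCK libraries held 10079 ± 2846 peaks (SD, n = 2) and SIRT1OE libraries 10006 ± 1016 (SD, n = 2), with an exact two-sided permutation p of 1.0. Peaks covered 2.90 ± 0.780 Mb in MOCK and 2.82 ± 0.312 Mb in SIRT1OE (SD, n = 2 each; exact permutation p = 1.0). The sign of both differences rested on single libraries. Without MOCK 1 the SIRT1OE mean was higher by 1940 peaks and 0.47 Mb, and without SIRT1OE 2 it was higher by 645.5 peaks and 0.139 Mb. Peaks with a −log10 q of 5 or more numbered 2196 ± 439 in MOCK and 1874 ± 426 in SIRT1OE (SD, n = 2 each; exact permutation p = 0.667). Peaks with a fold enrichment of 5 or more, by the authors' value for each peak, numbered 2297 in MOCK 1, 1843 in MOCK 2, 1251 in SIRT1OE 1 and 1166 in SIRT1OE 2. Both SIRT1OE libraries thus lay below both MOCK libraries, at the smallest p this test allows (exact permutation p = 0.33). The background level was also higher in both SIRT1OE libraries than in both MOCK libraries.

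Strong peaks were found again in the other library of the same group, and weak peaks mostly were not. In the decile of each list with the highest −log10 q, 88.4% of MOCK 1 peaks, 97.9% of MOCK 2 peaks, 87.7% of SIRT1OE 1 peaks and 90.0% of SIRT1OE 2 peaks overlapped a peak of the other library of the group by at least 1 bp. In the lowest decile the shares were 9.83%, 19.8%, 9.69% and 10.4%. The top decile was recovered nearly as often by libraries of the other group, at 84.8% for MOCK 1, 90.2% for MOCK 2, 86.9% for SIRT1OE 1 and 91.9% for SIRT1OE 2. A missing call in a library is not a measured absence of 5hmC.

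**Figure D1:**
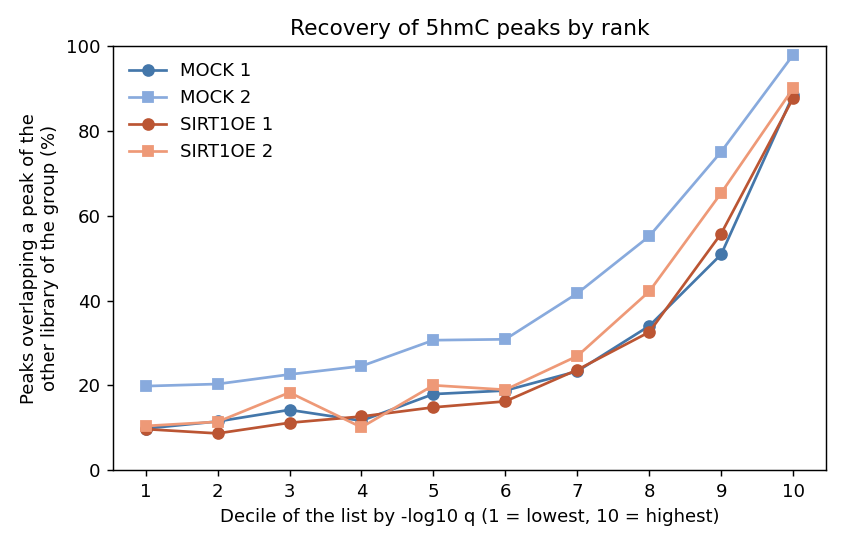
Share of peaks (%) that overlap a peak of the other library of the same group, by decile of each list ordered by −log10 q, with 1 line per library. Recovery in the highest decile lies between 87.7% and 97.9%, and in the lowest between 9.69% and 19.8%.

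Libraries of 1 group shared somewhat more peaks than libraries of different groups. The MOCK libraries shared 33.6% of their peaks and the SIRT1OE libraries 29.2%, while the 4 pairs across groups shared 28.4%, 25.9%, 27.9% and 27.3%. The mean was 31.4% within groups and 27.4% between them, a difference of 4.01 percentage points. In base pairs the mean Jaccard index was 18.9% within and 16.2% between groups. Random placement on the same chromosome gave shares between 0.25% and 0.33%, and placement inside the same 5 Mb bin gave at most 0.56% on average. Of the 3 ways to pair the 4 libraries, the true one gave the highest overlap, which cannot be told from chance with so few pairings. The difference was 1.58 percentage points without MOCK 1, 2.05 without MOCK 2, 6.98 without SIRT1OE 1 and 5.42 without SIRT1OE 2.

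Joining overlapping peaks gave 28695 regions. Of these, 22453 regions (78.3%) were called in 1 library and 1533 (5.34%) in all 4. A set of 681 regions was called in both SIRT1OE libraries and in neither MOCK library, and 942 regions were called in both MOCK libraries and in neither SIRT1OE library. The 2 other ways to split the libraries also gave such regions. MOCK 1 with SIRT1OE 1 against the rest gave 743 and 235 regions, and MOCK 1 with SIRT1OE 2 against the rest gave 432 and 342. The total was 1623 regions for the true split and 978 and 774 for the others, whereas random placement on the same chromosome gave 27.7 regions called only in the SIRT1OE pair and 27.9 called only in the MOCK pair on average. Placement inside the same 5 Mb bin gave 53.9 and 49.1. Among peaks with a −log10 q of 5 or more, 124 regions were specific to the SIRT1OE pair and 202 to the MOCK pair. Among peaks with a fold of 5 or more the numbers were 77 and 278. At that threshold the lists of both SIRT1OE libraries were shorter than those of both MOCK libraries, so these numbers were not on equal terms. No single region was tested, because Fisher's exact test of 2 calls against 2 cannot go below p = 0.33.

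**Figure D2:**
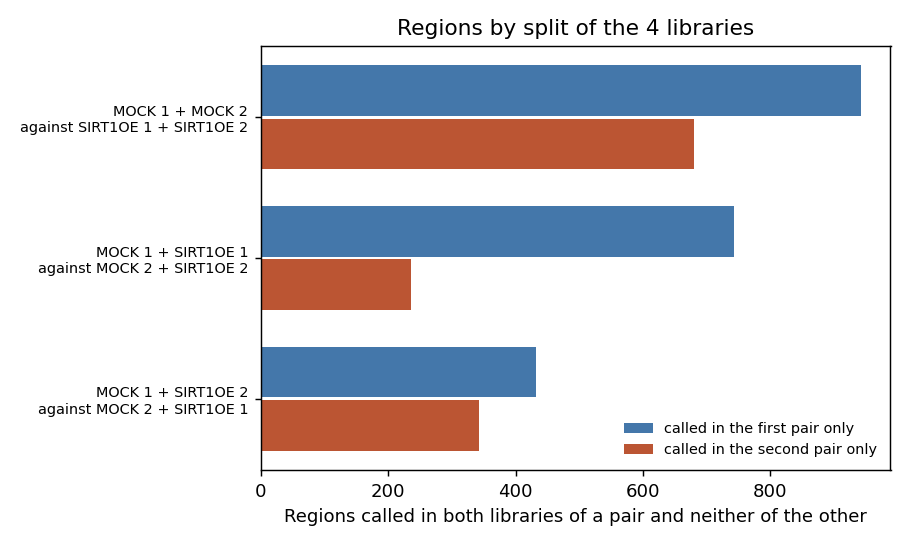
Number of regions called in both libraries of a pair and in neither library of the other pair, for the 3 ways to split the 4 libraries. The true split, at the top, holds 942 and 681 regions, and the splits that mix the groups hold 743 and 235, and 432 and 342.

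Among the 12 highest-ranked regions called only in the SIRT1OE pair, the first lay on chromosome 15 from 75586831 to 75587097 (hg19), with a fold enrichment of 5.46 in SIRT1OE 1 and 5.12 in SIRT1OE 2. The next lay on chromosome 13 from 21951425 to 21951954, with folds of 6.17 and 5.46. A region on chromosome 4 from 132664368 to 132665117 had folds of 6.15 and 6.12. Regions on chromosome 2 from 129745651 to 129745957 (folds of 6.46 and 5.96) and on chromosome 1 from 164870428 to 164870718 (folds of 5.90 and 5.96) stood over a local background equal to the genome background. Of the 12 regions, 5 had a local background under 2 times the genome background and 3 one of over 4 times. Genes at these positions were not analysed here, because the annotation at hand was for another genome build.

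Of the 12 highest-ranked regions called only in the MOCK pair, 7 stood over a local background of more than 4 times the genome background. The first, on chromosome 4 from 49157396 to 49157690, had a local background of 11.7 times the genome background and folds of 3.76 in MOCK 1 and 3.83 in MOCK 2. The 3 regions with a background under 2 times had the highest folds. They lay on chromosome 1 from 11516371 to 11516631 (folds of 8.78 and 7.72), on chromosome 2 from 42267488 to 42267825 (7.32 and 7.74) and on chromosome 1 from 2960833 to 2961193 (7.62 and 6.80). Local backgrounds above 4 times the genome background occurred in 11.7% of all regions specific to the SIRT1OE pair, 6.58% of those specific to the MOCK pair, 17.7% of regions called in all 4 libraries and 0.9% of those called in 1.

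The 6 highest-ranked regions called in all 4 libraries all lay within 5000 bp of the outermost peak of a chromosome. They included chromosome X from 155259591 to 155260484, chromosome 18 from 9931 to 10780 and chromosome 5 from 9959 to 11968. The number of fragments at their summits lay between 152 and 229 in every library. Of the 6 regions, 4 stood over a local background of more than 4 times the genome background in at least 1 library, and 0 over one of under 2 times. The region on chromosome X did so only in SIRT1OE (4.73 in both libraries, against 3.80 and 3.17 in MOCK). The region on chromosome 4 from 191043462 to 191044302 did so only in MOCK (5.70 and 6.02, against 2.52 in both SIRT1OE libraries).

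Peak density varied between chromosomes, and over the full span of each chromosome, chromosome 19 had the highest density in all 4 libraries. Without stretches of 1 Mb or more that held no peak, chromosome 21 was densest in MOCK 1 and MOCK 2 (1.96 and 2.47 times the mean, against 1.90 and 2.11 for chromosome 19), and chromosome 19 in SIRT1OE 1 and SIRT1OE 2. Over the full span, relative to the mean of the library, chromosome 19 held 2.37 ± 0.18 times as many peaks per Mb in MOCK and 3.53 ± 0.35 times in SIRT1OE (SD, n = 2 each), a log2 difference of 0.57. Chromosome 22 held 1.32 ± 0.04 times in MOCK and 1.91 ± 0.03 times in SIRT1OE (log2 difference 0.53), and chromosome 17 held 0.81 ± 0.02 and 1.12 ± 0.12 times (log2 difference 0.46). Chromosome 7 held fewer in SIRT1OE, at 0.54 ± 0.03 times against 0.77 ± 0.05 in MOCK (log2 difference −0.50), with a log2 difference of −0.67 on its long arm. Each of these 4 comparisons reached the smallest p of the test (exact permutation p = 0.33). Of the 23 chromosomes, 5 had both SIRT1OE libraries above both MOCK libraries and 5 had both below. Together these were 10 chromosomes (43.5%), where chance gives 33.3% for both directions together. The higher density on chromosome 19 was not present among strong peaks: the log2 difference was 0.03 with a −log10 q of 5 or more and −0.04 with a fold of 5 or more. For chromosome 22 these values were 0.11 and 0.15, for chromosome 17 they were 0.24 and −0.10, and for chromosome 7 they were −0.30 and −0.41. MDS-L comes from a case with a deletion in the long arm of chromosome 5. That arm held 0.60 ± 0.07 times the mean density in MOCK and 0.61 ± 0.13 times in SIRT1OE, and the short arm 1.32 ± 0.10 and 1.36 ± 0.19 times (SD, n = 2 each). Chromosomes 3, 13 and 14 held 0.60, 0.45 and 0.58 times in MOCK over their full spans, whereas the span of the arm left out the longest stretch without a peak. Without stretches of 1 Mb or more that held no peak, the values in MOCK 1 and MOCK 2 were 0.60 and 0.53 for chromosome 3. They were 0.60 and 0.58 for chromosome 13 and 0.70 and 0.59 for chromosome 14. The arm was not measured that way. Densities about as low thus occurred elsewhere, though over unlike spans. A link to the deletion was not tested.

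**Figure D3:**
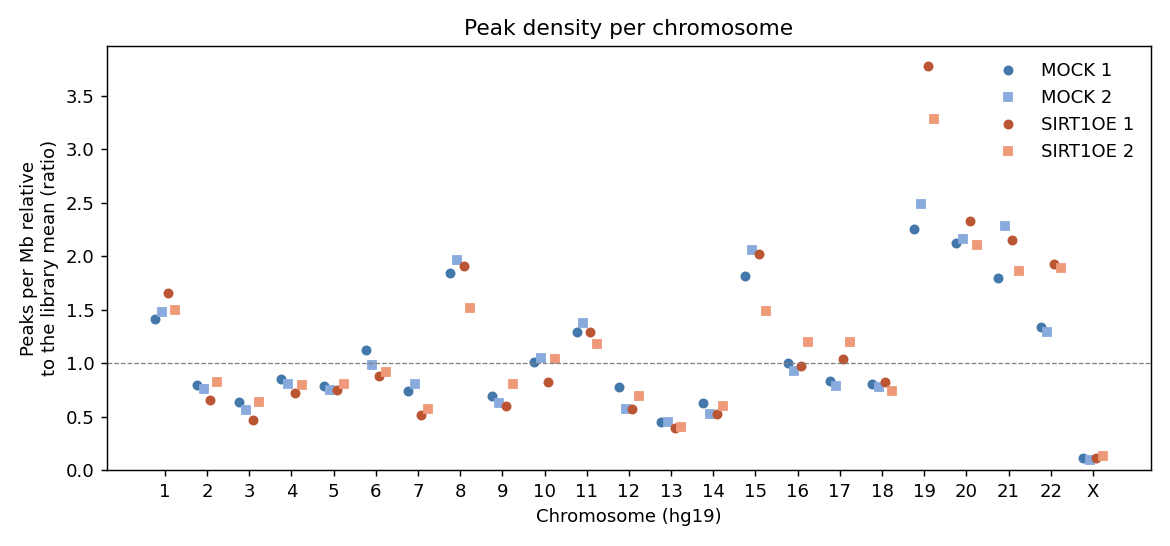
Peaks per Mb on each chromosome relative to the mean of the library (ratio), with 1 point per library. On chromosome 19 the MOCK libraries lie at 2.25 and 2.49 and the SIRT1OE libraries at 3.78 and 3.28, and on chromosome 7 the MOCK libraries lie at 0.74 and 0.81 and the SIRT1OE libraries at 0.52 and 0.57.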

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

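The test of adjoining bins was chosen after the pattern was seen, and the test on peaks with a fold of 5 or more was added once the test of the median fold had proved void. The local background under the peaks is not the 5hmC signal itself. It was at least 1.5 times the genome background (median per 5 Mb bin) over 2 stretches of 4 or more adjoining bins. Smaller or shorter rises lay elsewhere and were not listed, such as 1.27 times in the chromosome 1 bins from 0, 5 and 10 Mb and 1.77 times on chromosome 6 from 40 Mb. The median local background was 2.19 times the genome background on chromosome 15 from 60 Mb to the last bin, against 1.00 on the rest of that chromosome. On chromosome 8 from 40 Mb to the last bin it was 1.75 times, against 1.01 on the rest. The lists of all 4 libraries showed both stretches. The series has 2 input samples, and libraries of a group may share a control, so these may be 2 measurements rather than 4. On chromosome 15 the values ran from 2.15 to 2.22, slightly lower in SIRT1OE than in MOCK. On chromosome 8 they were 1.74 and 1.75 in MOCK and 1.74 and 1.78 in SIRT1OE.

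Bins with a median background of at least 1.5 times the genome background also held more peaks, with a median of 137 peaks over the 4 libraries against 48 in other bins. Of 57 such bins, 45 adjoined another, against a mean of 10.4 and a highest value of 25 in 1000 random draws, but this decides nothing, because the long stretches had prompted the test. As causes of the higher number of peaks in these bins, more copies of long chromosome segments in this cell line and more 5hmC per DNA copy cannot be told apart. The median fold of peaks was lower in these bins in 4 of 4 libraries, which decides nothing either, because a fixed p threshold admits lower folds over a higher background. Peaks with a fold of 5 or more, which the list threshold hardly limits, were 1.34 times as frequent per bin there (median of the libraries, range 1.14 to 1.42). That was below the 1.5 times that more 5hmC per DNA copy called for in every library and above the 1 that would have argued against it. The fold has 1 added to fragments and background, so a fold of 5 asks for less enrichment over a higher background. A ratio above 1 can arise from that alone. The 57 bins also include some with a far higher background, such as 70.0 times on chromosome 16 from 45 Mb. No copy number was measured here.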

How the results depend on the processing

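The alternatives for the 5 Mb bins, for the recovery by rank and for high input backgrounds, and those on chromosome density other than the −log10 q threshold, were chosen after seeing the data. With equal numbers of peaks or another overlap rule, regions specific to a pair numbered 581 to 713 for SIRT1OE and 761 to 934 for MOCK, and 617 and 898 without peaks over 4 times the background. With a −log10 q of 5 or more, 124 regions were specific to the SIRT1OE pair and 202 to the MOCK pair, and the log2 difference on chromosome 19 was 0.03. With a fold of 5 or more these values were 77, 278 and −0.04, and the overlap difference was 7.67 percentage points. Fewer peaks enter under both, so lower counts follow by construction, and the cause of the chromosome 19 change was not tested. Leaving out 1 library gave peak differences from −2086 to 1940, covered lengths from −0.633 to 0.47 Mb, overlap differences from 1.58 to 6.98, log2 differences on chromosome 19 from 0.47 to 0.68, 881 to 6894 SIRT1OE-specific and 1267 to 8078 MOCK-specific regions, where a lone library stands for its group.

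The 18 higher and 12 lower bins became 1 and 0 with a −log10 q of 5 or more (29 bins tested), 2 and 0 with a fold of 5 or more (9 tested), 0 and 1 in 10 Mb bins, and 5 and 6 without a minimum per bin. Centring on the median bin, which moved the median log2 difference from −0.07 to 0.12, gave 22 and 4. Leaving out 1 library gave 0 to 23 higher and 0 to 39 lower bins. In these fits 1 group has a lone library, assumed to vary like the other pair, which alone gives the spread. Without MOCK 1 or MOCK 2 limma called 0 bins (34 and 25 at an unadjusted p under 0.05), while log2 differences stayed about as large, at 1.22 and 1.69 for the first bin of chromosome 1 (1.46 with all libraries). The cause of the other changes was not tested. With the replicate number as a block the bins were 4 and 5, the difference in peaks was −73 and in length −0.082 Mb (exact sign-flip p = 1.0, smallest possible 0.5). Over 350 bins the deviations of same-numbered libraries correlated at −0.224, and the crossed pairing gave 20 and 15. Recovery of the top decile (91.0% on average) was 89.6% to 90.9% under the other overlap rules. Chromosome Y was left out throughout, and apart from it the lists hold only chromosomes 1 to 22 and X. The planned count over all sequences, taken without chromosome Y, is therefore the main count. Alternatives for annotation, gene lists and sequence were not run. Weak calls limit all counts of regions in 1 pair.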

Other observations

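The comparison of 5 Mb bins, the tests of depth and GC content, the repeat on bins chosen from weaker peaks and the values at chromosome ends were chosen after the values were seen. Of 350 bins tested with limma, 18 held a higher share of peaks in SIRT1OE and 12 a lower share. The fit gave every bin the spread of the trend over all bins (infinite prior degrees of freedom). The spread between a bin's own replicates therefore did not set its p-value. The bin on chromosome 8 from 50 Mb was called lower with 31 and 21 peaks in MOCK and 25 and 6 in SIRT1OE. Its log2 difference was −1.03, and −0.15 without SIRT1OE 2. The higher bins included the last bin of chromosome 8 from 145 Mb, with 16 and 8 peaks in MOCK and 45 and 32 in SIRT1OE (log2 difference 1.68, adjusted p = 3.4e-06), and the first 5 Mb of chromosome 1, with 68 and 63 peaks in MOCK and 186 and 179 in SIRT1OE (log2 difference 1.46, adjusted p = 0.00028). Chromosome 19 held 5 of the 18. The lower bins included chromosome 7 from 130 Mb, with 34 and 21 peaks in MOCK and 13 and 7 in SIRT1OE (log2 difference −1.45, adjusted p = 0.00045), and 7 of the 12 lay on chromosome 8, all of them in its stretch of raised local background from 40 Mb, which also held 2 higher bins. Bins with a background of at least 1.5 times the genome background made up 7 of the 12 lower and 3 of the 18 higher bins. Those 7 lower bins were the same 7 on chromosome 8. The bins of chromosome 15 from 60 Mb, with backgrounds of 2.08 to 2.25 times, were called neither higher nor lower. The share of such bins among all 350 tested is not given here, so no link between background and calls can be read from these numbers. Centring on the median bin gave 22 higher and 4 lower bins. In 50.3% of bins both SIRT1OE libraries lay on 1 side of both MOCK libraries, where chance gives 33.3%. The 2 other splits of the libraries gave 0 calls with limma (2 and 8 bins at an unadjusted p under 0.05), and 3 splits are too few for a share under 0.05. Each side of those splits held 1 MOCK and 1 SIRT1OE library. Any difference between the groups therefore widened the spread in these fits, so their low counts are no measure of chance calls. Leaving out MOCK 1 or MOCK 2 gave 0 calls with limma (34 and 25 bins at an unadjusted p under 0.05), in fits whose spread comes from the SIRT1OE pair alone. The log2 differences stayed about as large, at 1.22 and 1.69 for the first bin of chromosome 1. Leaving out SIRT1OE 1 gave 22 higher and 39 lower bins and leaving out SIRT1OE 2 gave 23 and 19, in fits whose spread comes from the MOCK pair alone, so the leave-outs do not show which libraries the calls rest on. Bins of 10 Mb gave 0 higher and 1 lower.

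Depth as the whole cause was not excluded, because the background level that stands for it here also rises with fragment length. SIRT1OE 2 and MOCK 1 had close background levels. Their contrast followed that of SIRT1OE 1 and MOCK 2 with a slope of 0.548 ± 0.051 (SE over bins, which are not independent replicates). Depth alone called for less than 0.25, if these levels measure depth. The contrast of SIRT1OE 2 and MOCK 2 followed that of SIRT1OE 1 and MOCK 1 with a slope of 0.388 ± 0.062 (SE over bins), for which no bound was set. Weak calls as the whole cause were not excluded. Among peaks with a −log10 q of 5 or more, the log2 ratio of peaks in the 18 to the 12 bins differed by 0.80 ± 0.35 (SE) between the groups, but those peaks had helped to choose the bins. In 14 higher and 10 lower bins chosen on the weaker peaks alone the difference was 0.34 ± 0.29 (SE). A different input background cannot be told apart, with a median log2 difference of −0.06 ± 0.055 (SE) in the 104 regions inside the 18 higher bins that were called in all 4 libraries and 0.01 ± 0.057 (SE) in the 26 such regions inside the 12 lower bins, nor can GC content, for which 0 of the 350 bins had a value here; a biological effect of SIRT1 stays open, untested.

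The first and last bins of chromosomes held 9.87 ± 0.66% of peaks in MOCK and 14.2 ± 0.07% in SIRT1OE (SD, n = 2 each; exact permutation p = 0.33, the smallest of this test). The outermost peak on each side of a chromosome was also examined, at 46 positions. At 21 of these 46 a region called in all 4 libraries lay within 5000 bp of that peak. The first and last bins numbered only 41, so some of the 46 outermost peaks lay further inside a chromosome. The 21 of 46 is therefore not a share of true chromosome ends.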
